A study of Listeria monocytogenes with 18 samples.

How the data were processed

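Total RNA depleted of ribosomal RNA was sequenced from 18 samples of *Listeria monocytogenes* strain 10403S, 3 for each combination of PAA (2.5 or 0.0 ppm) and time (0, 5 or 15 min). Per the labels' protocols, RNA was stabilised at the end of each incubation, ribosomal RNA was removed by hybridisation, libraries were made with the NEBNext Ultra II RNA kit, and the replicates came from independent cultures and RNA isolations. Per the submitters' processing notes, the tools included Trim Galore 0.6.0, cutadapt, FastQC, STAR 2.7.0e, HTSeq and DESeq2 1.26.0. The genome build and the annotation are not given in the sources used here.

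The deposited files are gene count tables in the STAR layout, with whole-number read counts that the authors did not normalise. Each table holds 4 rows of read classes that name no gene, which stayed out of library sizes and tests, and 3102 features with an unstranded column and a column for each strand. Uniquely mapped reads numbered 14166065 to 20561257 per library. Ambiguous reads, which overlap more than 1 feature, made up 23.8% to 41.7% of these, and reads in no feature 0.0443% to 0.0981%. Multimapping reads, left out of gene counts, made up 0.169% to 0.737% of all reads in 17 libraries and 4.49% in control 5 min replicate 1. Unmapped reads made up 1.19% to 1.99%.

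By a rule set before the data were examined, the unstranded column was the main one unless a stranded column held at least 80% of the stranded counts, and the first stranded column held 54.2%. Of 2768 features with over 200 stranded reads, 2584 had at least 90% of them in 1 of the stranded columns, 1334 in the first and 1250 in the other. Without strand, reads of a gene and its antisense partner cannot be told apart, and reads where features overlap are counted for none of them. The transfer-messenger RNA, the RNase P RNA, the signal recognition particle RNA and the 6S RNA therefore have 0 counts in the unstranded column. A strand-resolved table was added after the data were seen, which takes for each feature the stranded column with the larger total and leaves out 5 repeated features. It was used for those RNAs and as an alternative. The strand of the features is not given, so where features overlap this column may hold reads of another feature.

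The features with locus tags are not paired with gene names in the files. The reference table at hand is that of strain EGD-e (assembly ASM19603v1), and 0 of the 2909 locus tags and 13 of the named RNAs matched it. The 24 gene lists fixed before the data were examined (peroxide and oxidative stress; class I and III heat shock; SOS and DNA repair; SigB general stress; cobalamin synthesis, propanediol and ethanolamine utilisation; iron and other metals; nucleotide and amino acid synthesis; ribosomal proteins and aminoacyl-tRNA synthetases; ATP synthase, respiration and sugar transport; virulence; flagella; cell envelope stress; phage) had 0 measured members each, so no list was tested, and the genes chosen beforehand by name are not analysed here. At most 2 locus tags that were higher and 2 that were lower with PAA are printed.

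Each comparison of 2 groups was fitted to its 6 libraries with edgeR 4.0.16 under R 4.3.3: filterByExpr, trimmed mean of M values (TMM), robust quasi-likelihood fit and test, and Benjamini-Hochberg adjustment with a threshold of 0.05. Differences of PAA effects between times were contrasts in a fit of all 18 libraries. The fold changes are model estimates, each with a standard error (SE) derived from the estimate and its quasi-likelihood test statistic. Log2 CPM used a pseudocount of 0.5 CPM. Principal components and shares of variance used the 2795 features kept in the fit of all 18 libraries. The genes to be named were to have an adjusted p under 0.05, a fold change of at least 2, a mean of at least 20 counts, no overlap between groups and a name. For features called only with the culture as a block, the same direction in each culture replaced the condition on overlap, a change made after the data were seen, and up to 5 small RNAs were taken per direction. The RNAs rli39, rli55, rli47, the LhrC copies and the structural RNAs were chosen after the data were seen.

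Whether replicate numbers pair the samples was checked before the fits were compared. Libraries with the same number deviated together from their group means in 15 of 15 pairs of libraries, 1 pair per number in each comparison of 2 groups. Their correlations were 0.359 to 0.920, each pair correlated best with its own number, and the highest correlation across numbers was 0.221. The pairing comes from this check and from the labels, which number the growth replicates, and the number is called the culture in the text. RNA isolation was also independent between replicates, so effects of culture and of isolation cannot be told apart. Libraries of a group differed far beyond sampling noise (chi-square per degree of freedom 304 to 690), so none was counted as a duplicate.

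The fits were tested on simulated data with the real means, library sizes and culture differences and 200 changed genes. With the block at 15 min, 53.7% of 1.5-fold, 88.1% of 2-fold and 98.5% of 4-fold changes were recovered among 2701 features, with 10 false calls of 170. At 5 min the shares were 19.4%, 77.6% and 97.0% of 2740 features, and at 0 min 68.7%, 89.6% and 100% of 2742. Without the block, 0% of the changes of any size were recovered in the comparisons of 2 groups, so a low count in those fits does not show that few features changed.

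The alternatives were DESeq2 1.42.0 with its size factors, edgeR with DESeq2-type size factors, library totals alone, no filter on low counts, the culture as a block, the larger stranded column, the named RNAs left out, all 18 libraries in one fit, a fold threshold of 2 and each library left out in turn. Strand-resolved counts, combinations with the block and the block without each culture were added after the data were seen. Single values were compared with exact permutation tests in SciPy 1.17.1 under Python 3.11.15, and runs of neighbouring rows with 10000 random draws.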

Results

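RNA was sequenced from the wild-type strain 10403S of *Listeria monocytogenes*, a food-borne bacterial pathogen, to ask which transcripts respond to a low dose of PAA. The study's labels spell the compound paracetic acid, taken here to be peracetic acid, an oxidising disinfectant used on food and food-contact surfaces. Cells taken from growing cultures were held in Ringer's solution, a salt solution without nutrients, with PAA at 2.5 ppm or without it (0.0 ppm, control), and were sampled at 0, 5 and 15 min, where 0 min means within seconds of mixing. Each of the 6 combinations of treatment and time was represented by 3 libraries, 1 from each of 3 independently grown cultures, so that 18 libraries were compared. The count tables hold 3102 features, of which 2909 are genes listed by locus tag and 193 are small or structural RNAs listed by name. Total gene counts per library ranged from 8780631 to 14136372, with a median of 11038848.

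The cultures differed more than the treatments did. The first principal component of the log2 CPM (read counts scaled to a common library total) carried 40.5% of the variance, and the culture explained 91.2% of it. The second carried 31.0%, of which sampling time explained 74.0%. Over the whole profile, culture accounted for 51.1% of the variance, time for 28.0% and PAA for 2.68%. For this reason each count of changed features is given for the fit without the culture and, where it differs, for the fit with the culture as a block.

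**Figure D1:**
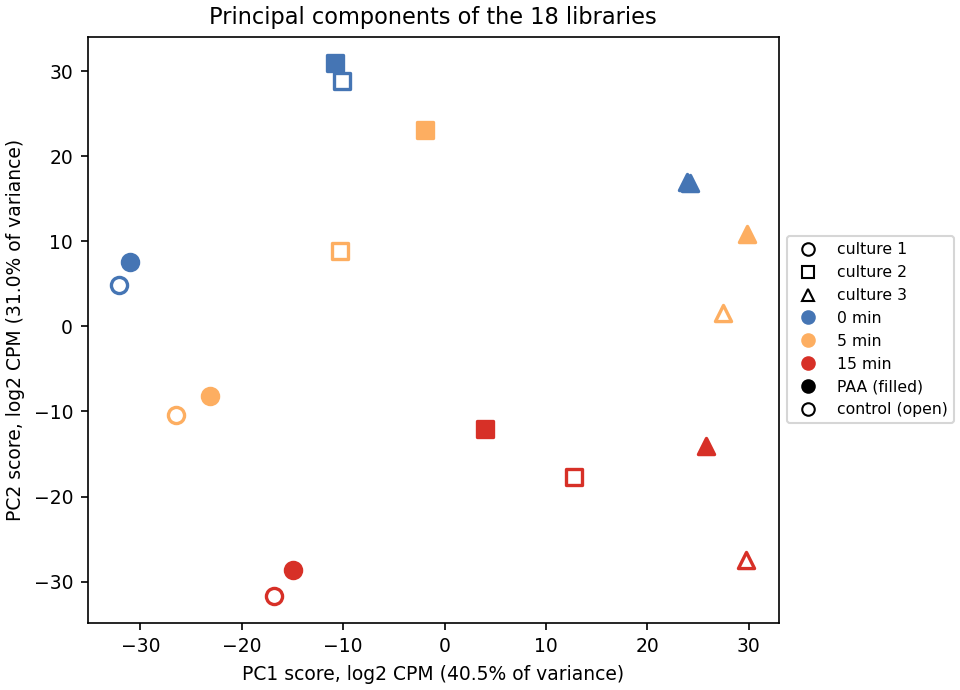
Scores of the 18 libraries on the first (x axis, 40.5% of variance) and second (y axis, 31.0%) principal components of log2 CPM. Shapes stand for the 3 cultures, colours for the sampling times, filled symbols for PAA and open symbols for control, with the cultures apart along x. The 15 min libraries lie lowest along y, while those of 0 and 5 min overlap.

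Among the structural RNAs, the transfer-messenger RNA rli19-ssrA, which rescues stalled ribosomes, was the most abundant by far, at 10.9% to 28.6% of uniquely mapped reads per library. Its share at 15 min was 22.1% ± 6.10 with PAA and 18.4% ± 2.95 in the control (SD, n = 3 each, exact permutation p = 0.5, two-sided). The differences within cultures 1 to 3 were -0.47, -1.45 and 12.8 percentage points, so the higher mean with PAA came from culture 3 alone. At 5 min the shares were 17.7% ± 7.39 and 17.8% ± 6.12 (exact permutation p = 1, n = 3), and at 0 min 16.1% ± 3.42 and 18.4% ± 5.87 (exact permutation p = 0.6, n = 3). The RNase P RNA rli15-rnpB, which matures transfer RNAs, took 1.38% ± 0.50 with PAA and 1.28% ± 0.0316 in the control at 15 min (SD, n = 3, exact permutation p = 1). Its differences within cultures 1 to 3 were -0.14, -0.20 and 0.64 percentage points. After adjustment over the 3 times, the lowest adjusted value for rli19-ssrA was 0.9 and that for rli15-rnpB was 1, by the Benjamini-Hochberg method on exact permutation p-values. These tests did not pair the libraries by culture. The smallest p that 3 libraries against 3 allow is 0.1, so they could not reach 0.05.

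Within seconds of mixing, no transcript was past the threshold between PAA and control. LMRG_RS11160 stood at 44.1 ± 5.54 CPM with PAA and 46.1 ± 5.75 CPM in the control, and LMRG_RS11155, listed in the neighbouring row, at 49.4 ± 24.1 and 48.9 ± 12.6 CPM (SD, n = 3 each). Their log2 fold changes with the culture as a block were -0.04 ± 0.13 and -0.04 ± 0.15 (SE). The small RNA rli32 stood at 0.43 ± 0.19 on the same scale, and 0 of 65 small or structural RNAs tested were past the threshold. The cobalamin riboswitch RNA rli39 stood at 2.62 ± 0.928 CPM with PAA and 3.48 ± 1.30 CPM in the control (SD, n = 3). With edgeR's quasi-likelihood test, 0 of 2742 features had an adjusted p under 0.05 and 0 had an unadjusted p under 0.05. DESeq2 called 0, with 2 at an unadjusted p under 0.05, and the blocked fits called 0 in edgeR, with 72 at an unadjusted p under 0.05, and 0 in DESeq2, with 49. With culture 2 left out, the blocked edgeR fit called 2 features, both lower with PAA.

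After 5 min of exposure, LMRG_RS11160 was higher with PAA in each of the 3 cultures. It reached 977 ± 374 CPM against 72.2 ± 3.38 CPM in the control (SD, n = 3 each), a 13.3-fold difference, with a log2 fold change of 3.73 ± 0.41 (SE). The edgeR adjusted p was 0.0233, and the log2 fold changes within cultures were 4.19, 3.89 and 2.93. LMRG_RS11155 stood at 392 ± 307 CPM with PAA and 56.2 ± 15.5 CPM in the control (SD, n = 3), with a log2 fold change of 2.77 ± 0.58 (SE) that varied from 1.39 to 4.26 between cultures and did not pass the edgeR test (adjusted p = 0.999). With the culture as a block its edgeR adjusted p was 0.179 in the 6 libraries of this time and 0.0298 in a fit of all 18. The small RNA rli32 had a log2 fold change of 0.66 ± 0.27 (SE) and rli39 one of -1.36 ± 0.40 with the block, and neither passed the edgeR test (adjusted p = 0.499 and 0.392).

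At this time edgeR called 1 of 2740 features with and without the block, DESeq2 called 2, and DESeq2 with the block called 14, of which 2 were higher and 12 lower. The call of LMRG_RS11160 was lost, with 0 features left, when control replicate 1, control replicate 2 or PAA replicate 2 was left out, and also when library totals alone set the scale; its log2 fold change in these settings was 3.72, 3.71, 3.69 and 3.71. Control replicate 1 was also the library with the largest share of multimapping reads, 4.49% against a median of 0.335%.

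**Figure D2:**
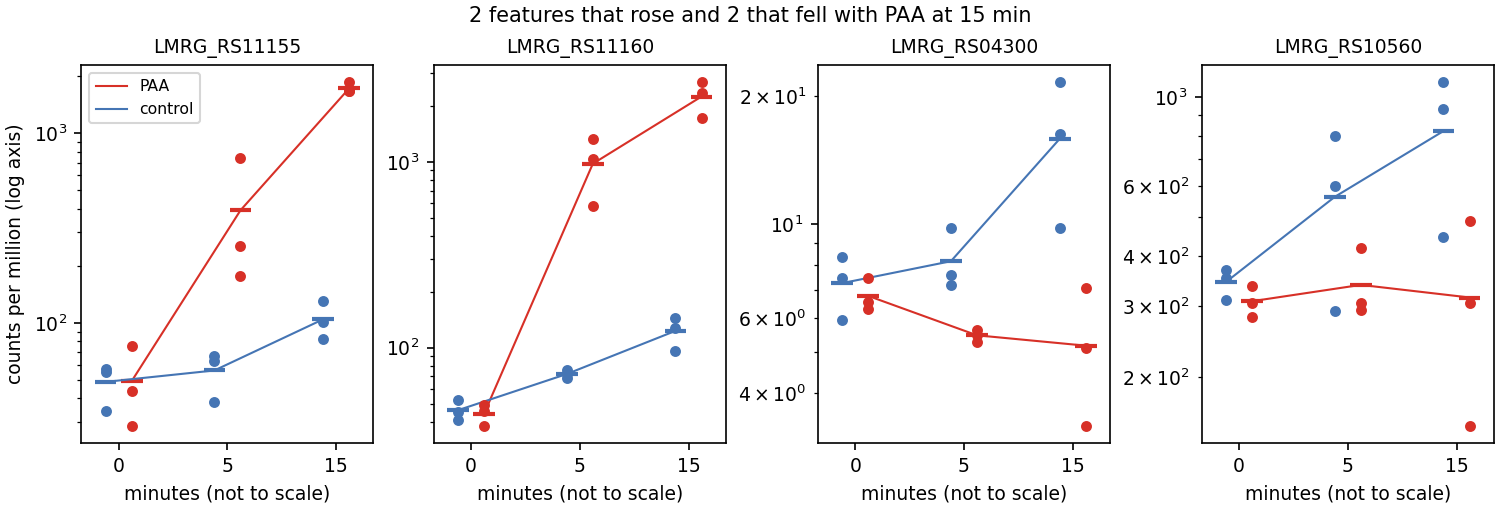
CPM (y axis, log scale) of 4 genes at 0, 5 and 15 min (x axis, not to scale), with each point a library, each bar the mean of 3 libraries and lines joining the means, in red for PAA and blue for control. LMRG_RS11155 and LMRG_RS11160 stood above the control in all 3 cultures at 15 min, whereas LMRG_RS04300 and LMRG_RS10560 averaged 15.8 and 822 CPM in the control and 5.17 and 316 CPM with PAA at that time.

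After 15 min, LMRG_RS11155 and LMRG_RS11160 were both strongly higher with PAA. LMRG_RS11160 reached 2248 ± 480 CPM against 123 ± 25.0 CPM in the control (SD, n = 3 each), 17.9-fold, with a log2 fold change of 4.16 ± 0.33 (SE, edgeR adjusted p = 0.00133). LMRG_RS11155 reached 1724 ± 109 CPM against 105 ± 24.1 CPM, 16.2-fold, with a log2 fold change of 4.02 ± 0.31 (SE, edgeR adjusted p = 0.00133). Within cultures the log2 fold changes of LMRG_RS11160 were 4.18, 4.16 and 4.20, and those of LMRG_RS11155 were 4.19, 4.32 and 3.66. These were the 2 features of 2701 that edgeR called without the block, and the count stayed at 2 when any library of this time was left out. DESeq2 called 3, all higher.

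With the culture as a block, edgeR called 111 features at 15 min, 54 higher and 57 lower with PAA. Of these, 27 were higher and 17 lower by at least 2-fold. Beyond LMRG_RS11155 (log2 fold change 4.04 ± 0.18 SE) and LMRG_RS11160 (4.16 ± 0.16), 2 further pairs of neighbouring genes rose by 1.69 to 2.91 and by 1.68 to 2.21. The median absolute log2 fold change of the 111 was 0.92. The largest differences below the control were those of LMRG_RS04300 and LMRG_RS10560. LMRG_RS04300 stood at 15.8 ± 5.89 CPM in the control and 5.17 ± 1.85 CPM with PAA (log2 fold change -1.59 ± 0.31 SE, edgeR adjusted p = 0.0122). LMRG_RS10560 stood at 822 ± 335 CPM and 316 ± 170 CPM (log2 fold change -1.47 ± 0.19 SE, edgeR adjusted p = 0.00107, SD over n = 3). Their means at 0 min were 6.77 and 309 CPM with PAA and 7.25 and 345 CPM in the control. The control means had thus risen, while those with PAA had changed little. In culture 3, however, the PAA levels went from 7.46 to 3.35 and from 283 to 151 CPM. The change over time with PAA was not tested. With culture 1, 2 or 3 left out, the edgeR adjusted p of LMRG_RS04300 was 0.0777, 0.302 and 0.233 and that of LMRG_RS10560 0.0235, 0.208 and 0.0517 with the block. Among the small RNAs, rli32 stood at 42.8 ± 27.1 CPM in the control (SD, n = 3) and at 0.424 times that level with PAA. Its log2 fold change was -1.24 ± 0.20 (SE, edgeR adjusted p = 0.00403), with -1.02, -1.22 and -1.29 within cultures. It was the only call among 63 small or structural RNAs in this fit, and the call was lost in the blocked fit of all 18 libraries (edgeR adjusted p = 0.201), which called 0 of 72 such RNAs. On strand-resolved counts the log2 fold change of rli32 was -0.83, short of 2-fold (edgeR adjusted p = 0.0281 with the block). With culture 2 or 3 left out its edgeR adjusted p with the block was 0.274 and 0.188, and without control replicate 3 its log2 fold change in the fit without the block was -0.68 against -1.29. The small RNA rli54 (log2 fold change -0.36 ± 0.15 SE), rli91 (-0.71 ± 0.24) and rli39 (-0.26 ± 0.29) were not past the threshold.

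Changed genes lay next to each other in the tables more often than random draws did. Of the 54 features higher with PAA, 14 pairs occupied neighbouring rows, where 10000 random draws of as many tested genes gave 1.01 on average and at most 6. Of the 56 lower genes listed by locus tag, 11 pairs were neighbours, against 1.10 on average and at most 7. The permutation p was 0.0001 in both directions, the smallest that this number of draws can give. The control over time showed the same excess. Between 0 and 5 min, 34 higher and 31 lower pairs were neighbours, against 4.92 and 6.24 on average. Between 0 and 15 min, 195 and 280 were, against 51.6 and 113. The draws treat genes as independent. Neighbours that vary together for any reason would give such an excess, so it does not test whether PAA caused the calls. With PAA at 15 min, the neighbours formed 10 runs of 24 higher features and 7 runs of 18 lower features, the longest with 5 genes in each direction. LMRG_RS11155 and LMRG_RS11160 made up the run with the largest fold changes, and LMRG_RS10560 headed a run of 2 lower genes. The log2 fold changes in the run of 5 higher genes ranged from 0.93 to 1.52, and those in the run of 5 lower genes from -1.25 to -0.66.

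The 111 calls rest on few degrees of freedom: with culture 1 left out the blocked fit called 40 features, and with culture 2 or culture 3 left out it called 2 in each case, while a blocked fit of all 18 libraries called 32, all of them among the 111 and with the same direction. The split by direction moved with the scaling, to 36 higher and 13 lower when library totals alone were used, a scale on which the median log2 fold change of all features was 0.13 in place of 0.00 with the trimmed mean of M values.

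**Figure D3:**
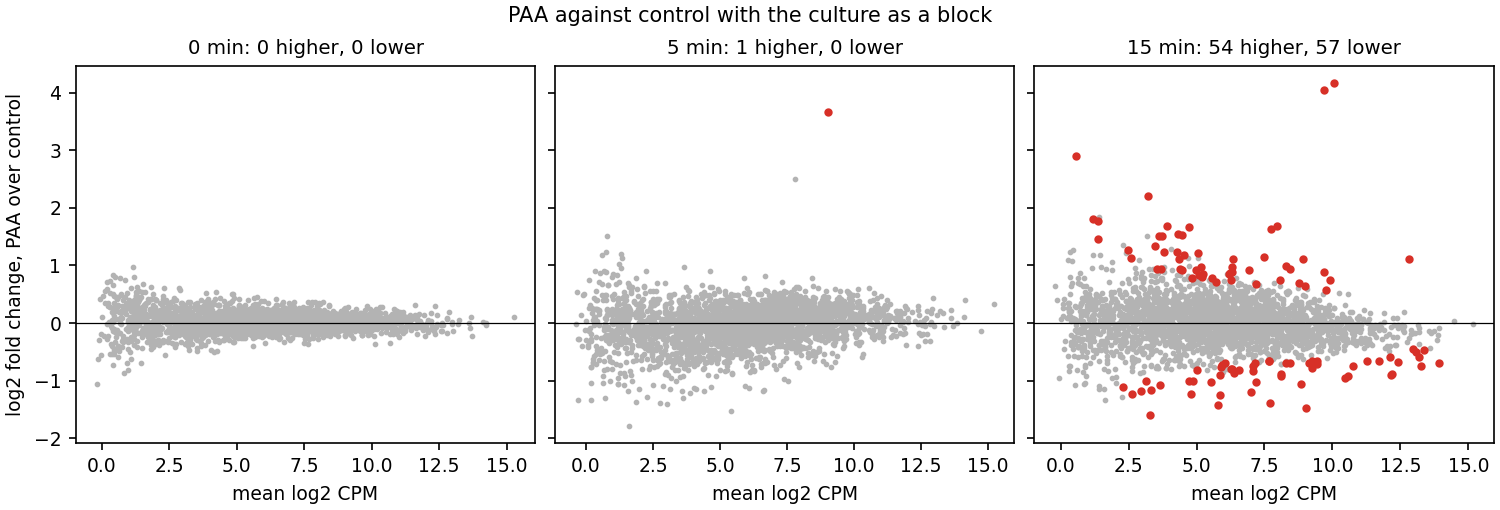
Log2 fold change of PAA over control (y axis) against mean log2 CPM (x axis) for each tested feature at 0, 5 and 15 min, from the edgeR fit with the culture as a block. Red points have an adjusted p under 0.05, and their number rises from 0 at 0 min to 1 at 5 min and 111 at 15 min.

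The growth of the response with time was tested directly in all 18 libraries. For LMRG_RS11160, the PAA effect at 5 min exceeded that at 0 min by 3.76 ± 0.41 on the log2 scale (SE, edgeR adjusted p = 0.000257), and the effect at 15 min exceeded that at 0 min by 4.25 ± 0.41 (SE, edgeR adjusted p = 5.29e-05). For LMRG_RS11155, the effect at 15 min exceeded that at 0 min by 4.02 ± 0.67 (SE, edgeR adjusted p = 0.0282), whereas its difference between 5 and 0 min, 2.72 ± 0.66, was not past the threshold (edgeR adjusted p = 1.00). These were the 1 and 2 features called of 2795. Between 5 and 15 min the PAA effect of LMRG_RS11155 differed by 1.31 ± 0.65 and that of LMRG_RS11160 by 0.49 ± 0.40, and edgeR called 0 features, with 24 at an unadjusted p under 0.05, and DESeq2 called 0, with 28. In simulated data this edgeR fit recovered 0% of 2-fold and 13.6% of 4-fold differences, and 22.4% and 75.8% with the block. The 0 calls therefore do not show that the response stayed the same. The difference for rli32 between 15 and 0 min was -1.55 ± 0.88 (SE, edgeR adjusted p = 1.00), so its PAA effect at 15 min was not shown to differ from that at 0 min. Leaving out single libraries changed the count for 15 against 0 min to 4 without PAA 15 min replicate 1, left it at 2 without control 0 min replicate 1 or PAA 0 min replicate 3, and lowered it to 1 without any of the others.

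Across features, the PAA log2 fold changes at 5 and 15 min had a Pearson correlation of 0.300 (Spearman 0.261, 2688 features), those at 0 and 5 min 0.251 (Spearman 0.309, Pearson 0.107 with DESeq2 and 0.0548 with no filter on low counts) and those at 0 and 15 min 0.0564 (Spearman 0.0821). Features are not independent replicates, and within cultures the correlation of 5 with 15 min ranged from -0.0692 in culture 2 to 0.477 in culture 3 and that of 0 with 5 min from -0.0451 in culture 3 to 0.361 in culture 2.

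Unexposed cells changed strongly during the same 15 min in Ringer's solution, which gives the background for the PAA comparisons. Among the small RNAs, rli54 rose from 161 ± 53.0 to 945 ± 461 CPM between 0 and 15 min (log2 fold change 2.45 ± 0.41 SE, 5.46-fold) and rli91 from 71.4 ± 37.1 to 364 ± 84.1 CPM (2.39 ± 0.28, 5.25-fold; SD, n = 3 each). Smaller rises were seen for RNA_19 (log2 fold change 2.28 ± 0.46 SE), rli88 (1.70 ± 0.30), rli123 (1.51 ± 0.43) and rli32 (1.37 ± 0.42). Falls were seen for lmos91 (-2.03 ± 0.47), rli108 (-2.01 ± 0.36), rli81 (-1.87 ± 0.44), RNA_43 (-1.52 ± 0.37) and rli145 (-1.45 ± 0.46). In all, 10 of 67 small or structural RNAs rose and 10 fell with the culture as a block, with edgeR adjusted p-values between 0.00154 for rli91 and 0.0393 for rli145 among those given here. The fall of rli145 was not past the threshold in the blocked fit of all 18 libraries (edgeR adjusted p = 0.0637). Nor was it on strand-resolved counts, which assign 4153 reads to rli145 in place of 726. There its log2 fold change was -0.52 ± 0.51 (SE, edgeR adjusted p = 0.459 with the block), with 1.24 in culture 3. Some of these values moved by over 1.5-fold when 1 library was left out of the fit without the block. The log2 fold change of lmos91, with a mean of 21.3 reads, was -1.25 without control 0 min replicate 1 and -3.16 without control 15 min replicate 1, against -1.97 in all 6. Without control 0 min replicate 2, that of rli108 was -1.51 against -2.10 and that of rli81 -1.25 against -2.06. On strand-resolved counts, the 6S RNA rli12-ssrS-6S, which binds RNA polymerase, rose from 182 ± 117 to 334 ± 197 CPM (log2 fold change 0.88 ± 0.24 SE, edgeR adjusted p = 0.0192 with the block).

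LMRG_RS11155 and LMRG_RS11160 also increased in the unexposed cells, by log2 fold changes of 1.06 ± 0.27 and 1.36 ± 0.27 (SE, edgeR adjusted p = 0.0180 and 0.00757 with the block, and 0.0550 and 0.000325 in the blocked fit of all 18 libraries). LMRG_RS04300 and LMRG_RS10560, lower with PAA, rose in the control by 1.02 ± 0.31 and 1.11 ± 0.27 (SE, edgeR adjusted p = 0.0340 and 0.0147 with the block). The 15 min control libraries enter both this comparison and the one with PAA, so a control value that is high by chance raises one and lowers the other.

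Without the block, edgeR called 12 of 2725 features between 0 and 15 min in the control, 6 higher and 6 lower, and DESeq2 called 385. With the block edgeR called 965, 391 higher and 574 lower. Without the block the count was 39 and 97 when control 0 min replicate 1 or replicate 3 was left out, and 0 when control 0 min replicate 2 or any 15 min control was, and with the block it was 4 when culture 2 was left out. With library totals alone the split was 14 higher and 40 lower without the block and 246 higher and 832 lower with it, on a scale whose median log2 fold change was -0.37 and -0.36, against -0.10 and -0.09 with the trimmed mean of M values, and with size factors of the DESeq2 type 15 were higher and 8 lower without the block.

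By 5 min, RNA_19 (log2 fold change 1.55 ± 0.31 SE), rli88 (1.36 ± 0.27) and rli91 (1.00 ± 0.26) had already risen in the control and rli145 (-1.70 ± 0.34) had fallen, with edgeR adjusted p-values of 0.00534, 0.00534, 0.0370 and 0.00534 with the block. These were the 4 calls among 66 small or structural RNAs. On strand-resolved counts the fall of rli145 was -0.71 ± 0.25 (SE) and missed the threshold (edgeR adjusted p = 0.0542 with the block). In the blocked fit of all 18 libraries 0 of 72 such RNAs were called, with edgeR adjusted p-values of 0.142 for RNA_19, 0.120 for rli88, 0.250 for rli91 and 0.154 for rli145. Without the block, the log2 fold change of rli88 was 1.54, and 0.68 without control 5 min replicate 2. In the same comparison LMRG_RS11160 rose by 0.67 ± 0.19 (SE, edgeR adjusted p = 0.0292 with the block and 0.191 in the blocked fit of all 18 libraries), while LMRG_RS11155 (0.21 ± 0.18) was not past the threshold. Over all 2737 features the blocked fit called 255, 121 higher and 134 lower, or 26 higher and 104 lower with library totals alone. Without the block edgeR called 0, with 36 at an unadjusted p under 0.05, and DESeq2 called 0, with 52, and the blocked count was 0 with culture 2 left out, 105 with culture 3 left out and 396 with culture 1 left out.

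**Figure D4:**
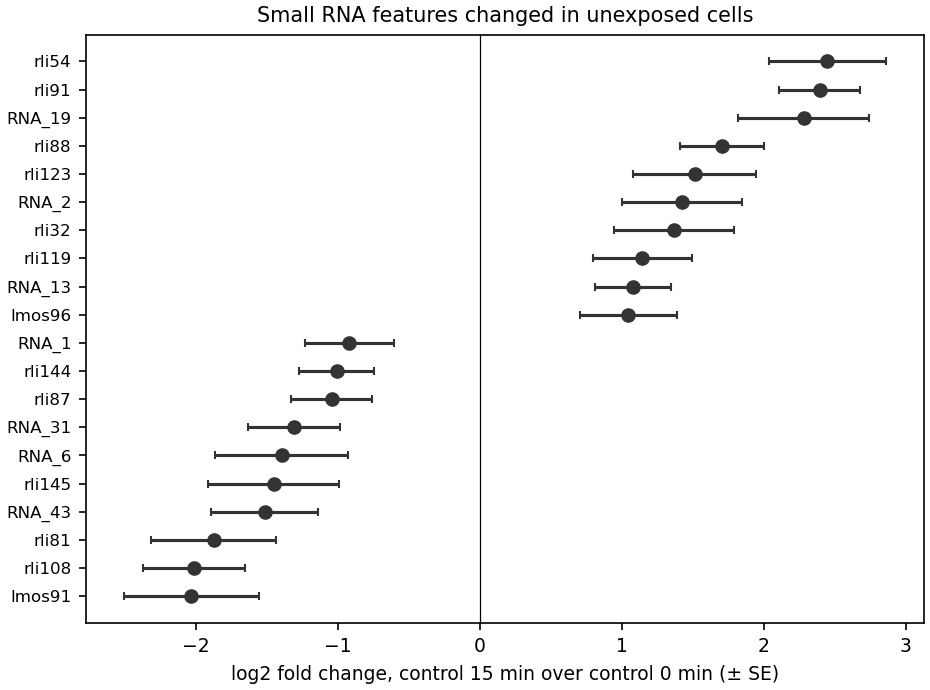
Log2 fold change between 15 and 0 min in the control (x axis) of the 20 small or structural RNAs called with the culture as a block, with bars for the standard error of the model estimate. Those above 0 rose and those below 0 fell, from rli54 at 2.45 to lmos91 at -2.03.

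Several regulatory RNAs of *L. monocytogenes* had too few reads for a comparison. The cell-envelope stress RNAs rli2-LhrC-2A, rli2-LhrC-2B, rli2-LhrC-2C and rli4-LhrC-4 held 5, 2, 3 and 2 reads in all 18 libraries together, and the stress-induced RNA rli47 held 0. The riboswitch RNA rli55, which governs ethanolamine utilisation, stood at 0.502 ± 0.507 CPM with PAA and 0.648 ± 0.50 CPM in the control at 15 min (SD, n = 3). Reads that map to several repeated copies are left out of the counts, so low counts of the LhrC copies do not show low expression. The copy rli7-LhrC-5 held 384 reads, and its PAA effect at 5 min exceeded that at 0 min by 1.04 ± 0.90 on the log2 scale, not past the threshold (SE, edgeR adjusted p = 1.00).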

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

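The comparisons between times and their tests were fixed before the data were examined, whereas the strand-resolved counts, the tests of explanations and the counts over other groupings of the libraries were chosen after the results were seen. The PAA effect on LMRG_RS11160 differed between 5 and 0 min (edgeR adjusted p = 0.000257) and between 15 and 0 min (edgeR adjusted p = 5.29e-05), and that on LMRG_RS11155 between 15 and 0 min (edgeR adjusted p = 0.0282), by a test of the difference itself. In the counts without strand, rli131 and rli113 had too few reads to be tested. On strand-resolved counts with the culture as a block, rli131 was higher with PAA at 15 min by 1.77 on the log2 scale (6.84 ± 2.17 against 2.21 ± 1.90 CPM, SD, n = 3 each, edgeR adjusted p = 0.0243). On the same scale rli113 was higher by 1.44 (4.12 ± 1.51 against 1.46 ± 0.383 CPM, edgeR adjusted p = 0.0215). Within cultures 1 to 3 the log2 fold changes were 0.32, 2.15 and 2.48 for rli131 and 0.83, 1.16 and 1.59 for rli113. The strand of these RNAs is not given, so the reads may come from features that overlap them. The blocked fit of these counts was not repeated with a culture left out. Without the block neither rli131 nor rli113 passed the edgeR test (adjusted p = 0.999 for both). In the control, rli131 fell from 7.98 ± 6.99 CPM at 0 min to 2.21 CPM at 15 min (log2 fold change -1.86 ± 0.33 SE, edgeR adjusted p = 0.00370 with the block). With PAA at 15 min it stood at 5.49, 9.34 and 5.68 CPM in cultures 1 to 3, against 15.8, 5.67 and 2.44 CPM in their controls at 0 min. The 15 min controls enter both comparisons.

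LMRG_RS11155 and LMRG_RS11160 occupy neighbouring rows and were both higher with PAA at 15 min. Reads from the strand opposite to the one read before exposure do not account for it. On the strand that held most of their reads in the 0 min controls, at least 97.3% of the reads of either gene lay in each PAA library at 15 min. The strand of the genes is not given, so which strand is antisense was not tested. Nor does a single culture, since the smallest of the log2 fold changes within cultures at 15 min was 3.66. A candidate explanation that stays open is induction of a shared transcript by PAA, which these counts, without gene names or coordinates, do not test. At 5 min the log2 fold changes in cultures 1 to 3 were 4.26, 2.02 and 1.39 for LMRG_RS11155. Those of LMRG_RS11160 were 4.19, 3.89 and 2.93, so the sizes differed in cultures 2 and 3. Reads shared with near-identical copies were not tested either, and multimapping reads are left out of the counts.

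For the differences between times, other groupings of the 18 libraries within each time were drawn 100 times with the real one included, in the fit without the block. For 5 against 0 min, 1 of 100 gave as many calls as the real grouping, which is the real one (1 call, highest other 0), and for 15 against 0 min likewise 1 of 100 (2 calls, highest other 0). These groupings mix the cultures, whose differences widen the spread in the fit without the block. In simulated data that fit recovered 6.06% and 7.58% of 4-fold differences for these 2 contrasts, so 0 calls from other groupings say little. Chance is therefore not excluded by them. With the culture as a block, PAA and control can be exchanged within cultures at the 2 times compared in 32 ways. As many calls as in the real grouping came from 8 of 32 for 5 against 0 min (1 call, highest other 1) and from 8 of 32 for 15 against 0 min (2 calls, highest other 5). The 7 others in each case exchange libraries at 0 min alone, where edgeR called 0 features, and they left as many calls in place. The 24 that exchange PAA and control of a culture at the later time gave 0 calls. That leaves 4 arrangements of the later time to compare, too few for a share under 0.05.

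For 15 against 5 min the real grouping gave 0 calls. All 100 of 100 groupings that mix the cultures and 32 of 32 within cultures reach at least 0 by construction, so these counts test nothing here. Of the 100, 97 gave 0 calls, and the highest other gave 465. That grouping set both libraries of culture 1 against both of culture 3 at each time, in opposite directions at 5 and 15 min, which points to the structure of cultures among the libraries, and the real count with the block is 0. Within cultures 30 of 32 gave 0 calls. The highest other gave 30 and exchanged all 3 cultures at 5 min, which turns the difference of the PAA effects into their sum.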

How the results depend on the processing

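Strand-resolved counts, the block combined with other settings, the block without a culture and the block for the correlations were chosen after the data were seen, and the other settings before. Of the alternative values for counts and correlations, 139 stayed within 1.5 times or the spread between cultures and 57 did not. For named features, set against the fit without the block, 293 values kept their side of the threshold, 118 passed it where that fit did not, 4 lost it and 0 changed direction. Of the 26 calls with the block given for named features, 3 were kept under each of 7 other settings with the block and 23 were lost under at least 1. With direction the same throughout, the losses numbered 0 with DESeq2 (2 without an adjusted p), 8 with all 18 libraries, 7 with library totals alone, 2 with strand-resolved counts, and 7, 23 and 4 without culture 1, 2 or 3 (1 not tested without culture 1). The 3 kept are LMRG_RS11160 at 5 and 15 min and LMRG_RS11155 at 15 min with PAA. The adjusted p of LMRG_RS04300 with PAA at 15 min ranged from 0.00154 in DESeq2 to 0.302 in edgeR without culture 2 over these settings. The replicate block, which removes the differences between cultures, raised the calls from 2 to 111 for PAA at 15 min, from 0 to 255 for control 5 against 0 min and from 12 to 965 for control 15 against 0 min, and changed no other count. The block with all 18 libraries gave 2 for PAA at 5 min, 32 at 15 min, and 18 and 1387 for the control at 5 and 15 min. The block with strand-resolved counts gave 128, 324 and 986 for PAA at 15 min and the control at 5 and 15 min, and the block with library totals alone gave 49, 130 and 1078. The block with DESeq2 gave 14 and 190 for PAA at 5 and 15 min, 323 and 1065 for the control at 5 and 15 min, and 2 and 5 for the differences between 5 and 0 min and between 15 and 0 min. The block with a culture left out, which leaves 4 libraries, gave 0 to 2, 1 to 2 and 2 to 40 for PAA at 0, 5 and 15 min, and 0 to 396 (105 without replicate 3) and 4 to 1064 (734 without replicate 1) for the control at 5 and 15 min. Without the block, PAA at 5 min gave 2 calls with DESeq2 and 0 with library totals alone. Control 15 against 0 min gave 385 with DESeq2, 23 with DESeq2-type size factors, 54 with library totals alone, 0 with the larger stranded column, 306 with all 18 libraries and 25 with strand-resolved counts. The larger stranded column holds few reads of the 1250 features with at least 90% of theirs in the other column. It tested 2110 features in place of 2725, so its 0 calls do not cover the same features. With single libraries left out, PAA at 5 min gave 0 to 1, control 15 against 0 min 0 to 97, the difference between 15 and 5 min 0 to 1 (1 without PAA 15 min replicate 1) and that between 15 and 0 min 1 to 4, while PAA at 0 and 15 min and control 5 against 0 min stayed at 0, 2 and 0. The correlation of PAA log2 fold changes between 0 and 15 min was -0.0442 with DESeq2. Except for the block and the fits with fewer libraries, by construction, the cause was not tested. The planned tests of gene lists with their alternatives were not run, since no list had a measured member. Without the block the spread between cultures limits the calls, since the block raised them from the same libraries. The role of depth was not tested. Among small RNAs both few reads and overlap between features limit what can be tested. Of these RNAs, 71 of 163 had fewer than 0.5 times their strand-resolved reads without strand, such as rli131 with 75 in place of 1851.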

Other observations

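The counts of calls in the comparisons of 2 groups, with and without the block, were fixed before the data were examined, whereas the strand-resolved counts, the slopes, shares and overlaps, the tests of explanations and the other groupings were chosen after the results were seen. The signal recognition particle RNA rli20-SRP, which takes part in protein export, varied widely between libraries, from 0.0846% to 0.949% of uniquely mapped reads, and on strand-resolved counts its log2 fold changes with PAA at 15 min differed in sign between cultures, at -0.37, 0.83 and -0.68 (-0.09 ± 0.20 SE with the block). The 6S RNA rli12-ssrS-6S, which rose over 15 min in the control, stood at -0.65 ± 0.21 (SE) with PAA against control at 15 min and did not pass the edgeR test (adjusted p = 0.0852 with the block).

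At 5 and 15 min, PAA differences ran against the change of the control over time. Of features higher in the control at 15 than at 0 min, 291 of 390 (74.6%) had a lower level with PAA at 5 min, and of those that fell, 477 of 574 (83.1%) had a higher level. Likewise, of features that changed in the control between 0 and 5 min, 94 of 121 (77.7%) of those that rose were lower with PAA at 15 min and 107 of 131 (81.7%) of those that fell were higher. These shares compare libraries that do not overlap, and features are not independent replicates. Among the 111 calls at 15 min, 15 were lower with PAA and rose in the control by 5 min, where independent lists would share 2.57, and 4 were higher with PAA and fell in the control, where independent lists would share 2.64.

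As a hypothesis, PAA may slow the change that cells undergo after transfer to Ringer's solution. The PAA difference within each culture was regressed, across 2795 features, on the time change in the controls of the other cultures, with no library in common. This change ran from 0 to 15 min for the 5 min pairs and from 0 to 5 min for the 15 min pairs. The slopes of the 2 times therefore differ in scale. The slope was negative in 6 of 6 pairs at 5 and 15 min, from -0.488 to -0.0244, with means of -0.0513, -0.302 and -0.304 in cultures 1 to 3. Over the cultures, which are the independent units, the mean was -0.219 ± 0.145 (SD, n = 3, exact sign-flip p = 0.25, two-sided, the smallest that 3 cultures can give), and the 95% t interval of -0.580 to 0.142 includes 0, so the test does not decide. The slopes were negative whether the share of transfer-messenger RNA was higher with PAA, as in 3 of 6 pairs, or lower. The same held for total counts, which were higher with PAA in 4 of 6 pairs. The sizes were not tested against each other. The largest difference in share, 12.8 percentage points in culture 3 at 15 min, had the steepest slope. The lowest, -10.7 points in culture 1 at 5 min, had the slope nearest 0. Culture 2 at 15 min, at -1.45 points, had a slope of -0.327 and goes the other way. A part of the shift tied to this share or to depth is therefore not excluded. An offset between tubes from the start is not excluded either. On a common axis, the control change from 0 to 15 min in the other cultures, the slopes at 0 min were -0.0405, -0.0522 and -0.00923, all below 0, and the later slopes -0.0398, -0.211 and -0.202. The mean of the later slopes on this axis was -0.151 ± 0.0964 (SD, n = 3), with a 95% t interval of -0.391 to 0.0885. The gap was 0.117 ± 0.103 (SD, n = 3, exact sign-flip p = 0.50), with a 95% t interval of -0.140 to 0.374. This offset, a difference in the moment of sampling or in handling between tubes with and without PAA that grows with time, and an effect of PAA on growth or energy state, stay open.

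The 6 libraries of each comparison of 2 groups can be grouped in 10 ways, the real one included, too few for a share under 0.05. PAA at 15 min gave 2 calls and control 15 against 0 min gave 12, where the highest other grouping gave 0, so that 1 of 10 was as large in each. PAA at 0 min and control 5 against 0 min gave 0, as did all 10 groupings. PAA at 5 min gave 1 call, which 2 of 10 groupings reached, and the highest other gave 115. That grouping set both libraries of culture 1 and the control of culture 2 against the rest, which follows the cultures, and the blocked value for PAA at 5 min is 1. With the culture as a block, groupings that part each pair number 4, the real one included. The real ones gave 111 calls for PAA at 15 min, 255 for control 5 against 0 min and 965 for control 15 against 0 min, and the highest other gave 0 in each. The others exchange PAA and control, or the times, within a culture.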
